A study of Mus musculus with 2 samples.

How the data were processed

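Single-cell RNA sequencing libraries of mixed liver cell suspensions (hepatocytes and non-parenchymal cells) were compared between a mouse liver 6 weeks after partial inferior vena cava ligation (pIVCL) and a control liver. Partial inferior vena cava ligation narrows the vein above the liver, which congests the organ and raises portal pressure. Each group held 1 library, assigned by the genotype label. The title of the control sample calls it healthy, and whether that animal had a sham operation is not given in the sources used here. The growth protocol given for both samples, the control among them, describes the ligation, so each pIVCL over Control comparison rests on the genotype label and the title. The number of animals behind each library is also not given in the sources used here.

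The authors deposited a gene by barcode matrix of UMI counts per library, in which each value is the number of distinct molecules of 1 gene seen with 1 barcode. Reads were counted with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes, and the annotation release they used is not given in the sources used here. The deposited counts are whole numbers that carry no normalization, and each file already held only barcodes with at least 500 UMIs. The files list 31053 genes, of which 30934 identifiers (99.6%) matched GENCODE release M21 for GRCm38, from which the printed coordinates come. The label's protocol gives a target capture of 12000 cells per library, beside 7042 barcodes for pIVCL and 3574 for Control in the files.

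Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs. The mitochondrial limit removed 1590 pIVCL barcodes (22.6%) and 848 Control barcodes (23.7%). Doublets were called per library with the Scrublet method in scanpy 1.11.5 at an expected rate of 6%. It called 10 barcodes in each library, 0.184% of pIVCL and 0.367% of Control, far below the expected rate. The caller therefore probably missed doublets in both libraries, and how many remain was not measured. The called barcodes were removed, which left 5436 pIVCL and 2716 Control cells with a median of 2005 and 5263.5 UMIs per cell.

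Cells of both libraries were clustered together, without batch integration, by the Leiden algorithm (leidenalg 0.10.2, resolution 1) on a graph of 20 neighbours built from 30 principal components of 2000 variable genes. The calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9. The 30 clusters were named from markers of 21 cell classes, of which 191 of 192 symbols were found, and are called by the class name with "-like". No cluster stayed unnamed, and 15 classes were present. Macrophage-like cells are the Kupffer-like and monocyte/macrophage-like clusters together, and LSEC stands for liver sinusoidal endothelial cell.

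With 1 library per group there was no test, and no p-value, standard error or number of changed genes is given. Differences have no replicate check and compare these libraries, not the conditions. UMIs were summed over the cells of a class and scaled by the class total to CPM. Levels carry exact Poisson intervals, shares exact (Clopper-Pearson) binomial intervals and ratios conditional exact binomial intervals, all at 95% and all covering counting error only. A count of 0 was given a floor of 3 UMIs. Log2 ratios (pIVCL over Control) had 20 CPM added to both libraries, which understates the ratio of low genes.

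The gene lists, cell markers, measures and most alternatives were fixed before the data were examined. Of 398 symbols in 32 lists, 393 were found, and Cxcl11 was among the rest and is not analysed here. A list's result is the median log2 ratio of members with at least 20 summed UMIs, given with its percentile among 10000 random lists of the same size matched on mean expression and with 95% of 1000 Poisson draws. Gene and list comparisons of a class needed at least 100 cells in each library, while levels of the chemokines are given for every class. The genes named are the CXCR3 chemokines and their receptor, 2 to 4 members of a list described (those with the largest absolute log2 ratio), and the 10 highest and 10 lowest genes of LSEC-like and macrophage-like cells (5 and 5 for the other classes). These had at least 30 summed UMIs and at least 50 CPM in the higher library. Mitochondrial and ribosomal protein genes, unnamed gene models, immunoglobulin and T cell receptor segments, and genes with at least a 10 times higher level in another class were left out of that ranking. Some genes that met these rules are not used here. Any other gene named was chosen after its values were seen.

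LSEC-like cells were called pericentral-leaning when they held more UMIs of a 12-gene pericentral endothelial list than of a 12-gene periportal list, and periportal-leaning when they held fewer. This lean is a range of a per-cell count, not a cell type. Shares of cells with a UMI were compared after each cell was thinned to 1000 UMIs.

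The gene ratios and list medians were tested on simulated data, with Poisson counts drawn from the real class means and library totals. These counts had no spread between cells or libraries. The simulation therefore checked the calculation, and not whether the intervals hold for real cells. In the simulation of LSEC-like cells, run on 11281 genes, 50 genes at each fold of 0.25, 0.5, 2 and 4 had median ratios of 0.250, 0.481, 1.95 and 4.02. Of 1006 unchanged genes, 95.3% had an interval that covered 1, against 93.0% in the macrophage-like and 92.0% in the hepatocyte-like simulation. Coverage of the changed genes ranged down to 90% and 88% in the latter simulations. Unchanged genes there had median ratios of 0.956 and 0.973, against 0.995 in the LSEC-like simulation. The totals included the raised genes, which shifts the CPM ratios of other genes. The intervals are exact for Poisson counts such as those drawn here, so the lower coverage of unchanged genes in the simulation goes with this shift. A list raised 2-fold in simulation lay at percentile 100, and 2 of 25 unchanged lists lay outside the central 95%. In the simulation of macrophage-like cells, run on 10006 genes, the medians were 0.241, 0.471, 1.92 and 3.98, and in that of hepatocyte-like cells, run on 11279 genes, they were 0.241, 0.492, 1.89 and 4.00.

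The alternatives were a stricter cell filter (at least 1000 UMIs, 500 genes and at most 10% mitochondrial UMIs), no cell filter, doublets kept, 2 other clustering settings, and 3 other scalings, among them the trimmed mean of M values of edgeR 4.0.16 (R 4.3.3). Others were other denominators for shares, classes set per cell from marker UMIs, other definitions of the lean, 5 CPM added, and at least 100 UMIs per list member. Added after the data were seen were the removal of the 6% highest doublet scores, LSEC-like cells with no leukocyte marker UMI, cells with at least 2000 UMIs, lean lists without Fabp4 and Cd36, Kupffer-like cells alone, and LSEC-like and hepatocyte-like cells without their cycling clusters.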

Results

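Liver cells of a pIVCL mouse liver and a control mouse liver were profiled by droplet single-cell RNA sequencing, with 1 library per group. The pIVCL library held 7042 barcodes and 38154000 UMIs, and the Control library 3574 barcodes and 24637681 UMIs. Among kept cells the pIVCL library was shallower, with a median of 2005 UMIs per cell against 5263.5, so levels are given as CPM, the UMIs of a gene scaled by the total of its cell class. Xist RNA was present in both libraries (24762 UMIs in pIVCL and 17860 in Control) while the Y-linked genes Ddx3y and Eif2s3y had 0 UMIs in both and Uty had 3 in pIVCL and 2 in Control.

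The first comparison asked whether macrophages made up more of the congested liver, as the series title states. Macrophage-like cells were 12.8% of Control cells (347 of 2716, interval 11.5% to 14.1%) and 17.8% of pIVCL cells (967 of 5436, 16.8% to 18.8%), a ratio of 1.39. Within them, monocyte/macrophage-like cells, whose cluster was led by F13a1, S100a4 and Ccr2, were 28 of 347 Control cells (8.07%, 5.43% to 11.5%) and 193 of 967 pIVCL cells (20.0%, 17.5% to 22.6%). Kupffer-like cells, the resident macrophages marked by Clec4f, Vsig4 and C1qa, were 11.7% of Control and 14.2% of pIVCL cells. B cell-like cells were 4.97% of Control cells (4.18% to 5.86%) and 19.0% of pIVCL cells (18.0% to 20.1%). Neutrophil-like cells numbered 3 and 88, and erythroid-like cells 4 and 68. LSEC-like cells were 40.9% of Control cells (39.1% to 42.8%) and 11.3% of pIVCL cells (10.5% to 12.2%), and hepatic stellate-like cells 6.70% and 1.58%.

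The direction of the macrophage share depended on its denominator. Among leukocyte-like cells, macrophage-like cells were 45.8% in Control (42.2% to 49.5%) and 36.4% in pIVCL (34.6% to 38.3%), a ratio of 0.795. Relative to macrophage-like plus LSEC-like cells they were 23.8% and 61.1%, a ratio of 2.57. The stricter cell filter gave a ratio of 1.05 (0.902 to 1.22) and classes set per cell from marker UMIs 1.04 (0.907 to 1.18), both with intervals that included 1. All shares also depend on how hepatocytes and non-parenchymal cells were mixed and on the depth gap, with macrophage-like medians of 2332 UMIs in Control and 1133 in pIVCL. Hepatocyte-like cells, 16.9% of Control and 34.0% of pIVCL cells, included shallow clusters. Cluster 1 held 18.3% of them in Control and 39.7% in pIVCL, at medians of 1478 and 1239 UMIs. Cluster 7 held 13.3% and 13.4%, at 700 and 818 UMIs. Whether these barcodes were whole cells was not tested.

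**Figure D1:**
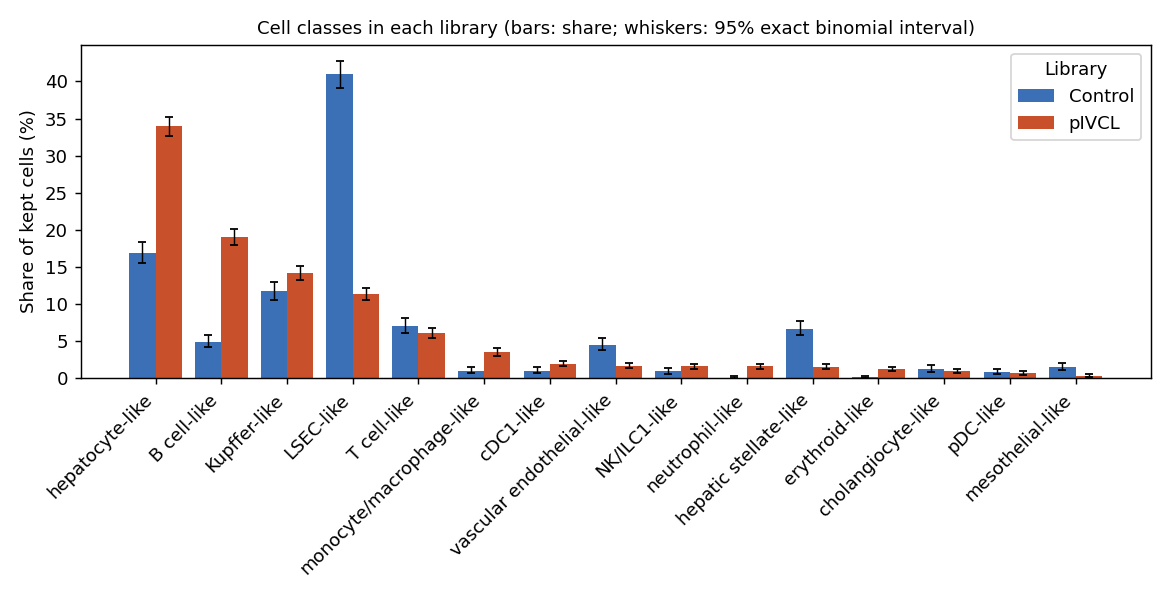
Share of kept cells (percent) in each of the 15 cell classes for the Control and pIVCL libraries, with exact 95% binomial intervals as whiskers. LSEC-like cells fill 40.9% of the Control library and 11.3% of the pIVCL library, while hepatocyte-like and B cell-like cells fill more of the pIVCL library.

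The second comparison asked whether sinusoidal endothelial cells expressed more Cxcl9 in the congested liver. Cxcl9 encodes an interferon-induced chemokine that attracts cells through the receptor CXCR3, and lies at chromosome 5, positions 92321347 to 92328079 of GRCm38, on the minus strand. In LSEC-like cells Cxcl9 stood at 275 CPM in Control (1732 UMIs in 1112 cells, interval 262 to 288) and 1137 CPM in pIVCL (2384 UMIs in 616 cells, 1092 to 1184), a ratio of 4.14 (3.89 to 4.40). Cxcl10, the neighbouring gene for another CXCR3 ligand, stood at 479 and 1567 CPM, a ratio of 3.27 (3.12 to 3.44). After thinning to 1000 UMIs, 17.2% of Control LSEC-like cells (161 of 935) and 51.0% of pIVCL LSEC-like cells (259 of 508) held a Cxcl9 UMI, while 177 and 108 shallower cells were left out. Before thinning the shares were 36.9% and 64.1%, at median depths of 6250 and 3053.5 UMIs. In hepatocyte-like cells, taken beforehand as a background class, the thinned shares were 0.792% and 0.985%, at median depths of 7569 and 2636 UMIs. Their summed Cxcl9 level was 10.5 CPM in Control and 17.9 in pIVCL, a ratio of 1.71 (1.33 to 2.22). Their Cxcl10 ratio was 4.41 (2.92 to 6.94). Whether hepatocyte-like cells expressed these genes or held RNA of other cells was not tested. In B cell-like cells, the other background class, Cxcl9 stood at 2.06 CPM in Control (1 UMI) and 2.88 in pIVCL (6 UMIs).

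LSEC-like cells held 85.1% of all Cxcl9 UMIs of kept Control cells and 73.7% of those of pIVCL cells. Vascular endothelial-like cells had 63.1 and 351 CPM of Cxcl9, a ratio of 5.56 (4.18 to 7.48), and hepatic stellate-like cells 37.3 and 296, a ratio of 7.92 (5.62 to 11.4), with 91 and 86 pIVCL cells, under the 100 required for other comparisons. Kupffer-like cells had 54.9 (43.2 to 68.8) and 63.9 (50.3 to 80.0), which did not differ beyond counting error, and monocyte/macrophage-like cells 123 and 43.9, from 32 and 43 UMIs. The level of the receptor Cxcr3 in T cell-like cells was 341 CPM in Control and 147 in pIVCL, a ratio of 0.430 (0.345 to 0.532).

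The Cxcl9 difference varied with the share of UMIs from the dissociation stress list, which holds immediate-early and heat shock genes. LSEC-like cells of both libraries were divided by that share into 3 groups of equal size. The ratio of pIVCL over Control was 1.74 (1.39 to 2.16) in the group with the lowest share, 1.54 (1.31 to 1.81) in the middle and 5.11 (4.64 to 5.65) in the highest. These groups also differed in depth. Median UMIs in Control and pIVCL were 2151.5 and 1153 in the lowest, 7400 and 2751 in the middle and 7593 and 3714 in the highest. The LSEC-like class also drew on different clusters in the libraries: cluster 3 held 752 Control and 4 pIVCL cells, cluster 5 held 19 and 437, and the shallow cluster 4 held 337 and 163. Every LSEC-like value given here therefore compares largely separate clusters.

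**Figure D2:**
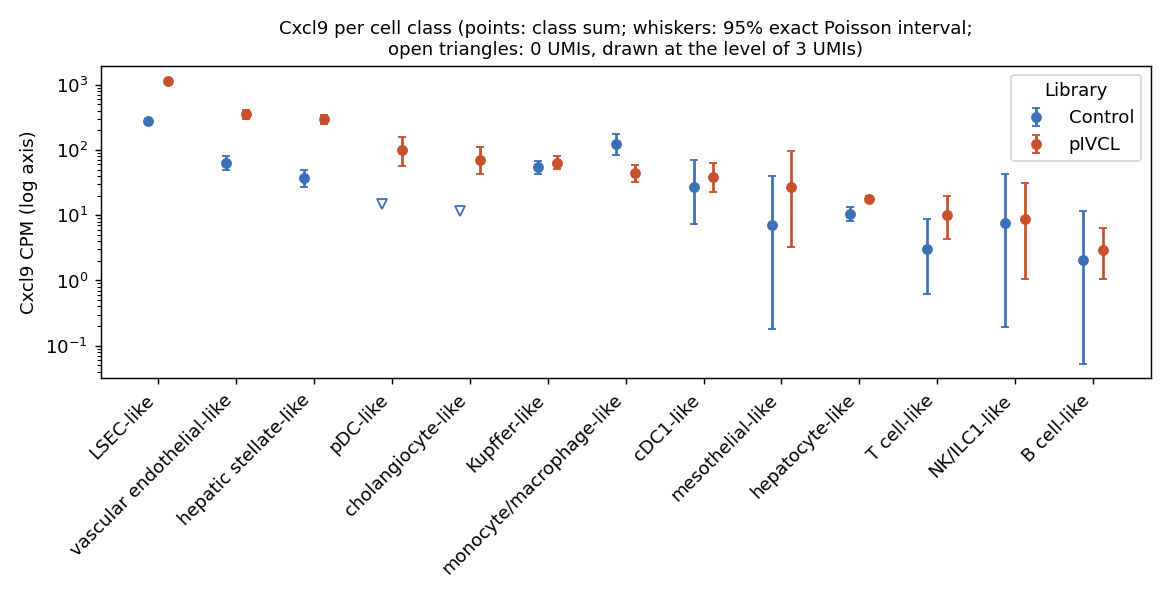
Cxcl9 level (CPM, log axis) in each cell class except neutrophil-like and erythroid-like cells of the Control and pIVCL libraries, with exact 95% Poisson intervals as whiskers and open triangles at the level of 3 UMIs where none was counted. LSEC-like cells have the highest level in both libraries, 275 CPM in Control and 1137 in pIVCL.

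The title of the series names a reversed zonation of Cxcl9, that is, a changed level between endothelium near the central vein and near the portal tract. Periportal-leaning LSEC-like cells had the higher Cxcl9 level in both libraries. In Control, Cxcl9 stood at 148 CPM in pericentral-leaning cells (412 cells, 133 to 165) and 365 in periportal-leaning cells (602 cells, 346 to 385), a pericentral over periportal ratio of 0.407 (0.361 to 0.458). In pIVCL it stood at 857 (285 cells, 804 to 912) and 1556 (273 cells, 1472 to 1643), a ratio of 0.551 (0.506 to 0.599). The level in pIVCL was 5.77 times that of Control in pericentral-leaning cells (5.11 to 6.54) and 4.27 times in periportal-leaning cells (3.95 to 4.61). For Cxcl10 the pericentral over periportal ratio was 0.731 in Control and 0.504 in pIVCL.

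The Cxcl9 ratio stayed below 1 in both libraries under each of the 14 alternatives run, from 0.324 to 0.428 in Control and from 0.260 to 0.594 in pIVCL. Which library had the higher ratio was less settled: with neighbour-averaged scores it was 0.324 in Control and 0.260 in pIVCL, and without Fabp4 and Cd36 it was 0.428 and 0.41. Fabp4, a pericentral list member, alone stood at 4818 CPM in pericentral-leaning pIVCL cells, where Wnt2 stood at 57.6, against 1236 and 624 in Control. Cells within 1 UMI of the boundary numbered 192 in Control (17.3%) and 128 in pIVCL (20.8%).

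**Figure D3:**
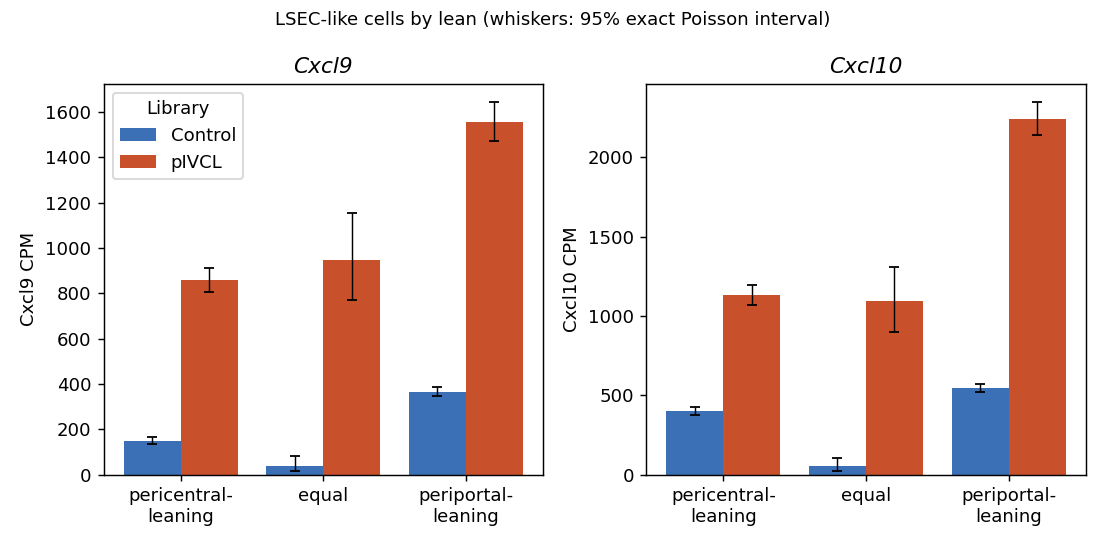
Cxcl9 and Cxcl10 levels (CPM) in LSEC-like cells grouped by lean, for the Control and pIVCL libraries, with exact 95% Poisson intervals as whiskers. Periportal-leaning cells have the higher Cxcl9 level in both libraries, 365 CPM in Control and 1556 in pIVCL.

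LSEC-like cells differed widely between the libraries beyond the chemokines. The highest log2 ratios were those of Esm1 (4.48, from 5.87 to 557 CPM), a marker of angiogenic endothelium, Selp (3.57), the adhesion molecule P-selectin, and Ctgf (3.36), a matricellular protein. Next came Abcc9 (3.22), Edn1 (3.13), which encodes the vasoconstrictor endothelin-1, Rgs2 (3.07), Odc1 (2.87), Fbln2 (2.83), Igfbp5 (2.71) and Cyr61 (2.57). Selp, Edn1 and Fbln2 are also markers used here to name vascular endothelial-like clusters. Cluster 5, with 70.9% of pIVCL LSEC-like cells, had a marker score of 2.24 for LSEC and 1.07 for vascular endothelial cells, its second class. Vascular endothelial cells within the LSEC-like class are therefore not excluded. The lowest were those of Cyp26b1 (-3.67, from 381 to 11.4 CPM), which degrades retinoic acid, Col13a1 (-3.00), Slco2a1 (-2.99), a prostaglandin transporter, and Wnt2 (-2.50), a Wnt ligand of pericentral endothelium. Below these stood Plxnc1 (-2.35), Hpgd (-2.29), Syne1 (-2.28), Car8 (-2.25) and Slc26a10 (-2.25). Esm1 lies at chromosome 13, positions 113209659 to 113218098, and Wnt2 at chromosome 6, positions 17988940 to 18030585.

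Of 15 LSEC identity genes, 13 were lower in pIVCL, with a list median of -0.64 (percentile 0 of matched random lists). Dnase1l3 had a log2 ratio of -1.91, the lectin Clec4g -1.43 and Fcgr2b -1.12, while Lyve1, a hyaluronan receptor, went the other way at 2.42. Of 12 pericentral endothelial genes 11 were lower (median -0.80, percentile 0), with Cdh13 at -1.86, Plpp1 at -1.85 and the exception Fabp4 at 2.37. The periportal list had a median of 0.56 (percentile 100), with 7 of 11 members higher, Dll4 at 0.89 and Adam23 at -2.08. Capillarization and basement membrane genes had a median of 0.50, with 10 of 11 higher, among them Plvap at 1.67 and Col4a1 at 0.76. YAP/TAZ targets had a median of 0.55, with 10 of 11 higher.

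Inflammatory adhesion and NF-kB genes were higher in pIVCL LSEC-like cells for 15 of 18 members (median 0.85, percentile 100), led by Selp, Vcam1 (2.26), Icam1 (2.10) and Sele (1.98). The interferon-gamma response list had a median of 0.26 (percentile 99.9), with 12 of 20 members higher, Irf8 at 1.51, Iigp1 at 0.86 and Irf1 at 0.81. The type I interferon response list had a median of 0.23, with 11 of 17 higher, among them Irf7 at 0.74 and Isg15 at 0.68. MHC class II genes had a median of 1.46, with all 7 measured members higher, while MHC class I genes had a median of -0.16. All 15 measured proliferation genes were higher (median 0.83), with Top2a at 1.42 and Mki67 at 1.37. Much of this lay in cycling cluster 29, with 4 Control and 12 pIVCL cells, without which the median was 0.28. Of 14 glycolysis genes 13 were higher (median 0.39). Shear response genes went both ways, with 5 higher and 5 lower (median 0.09), Edn1 at 3.13 and Thbd at -0.82.

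Transcripts of stress and of other cells moved with these groups. The 17 dissociation stress genes were all higher in pIVCL LSEC-like cells (median 0.96), led by Egr1 at 1.80 and Atf3 at 1.69. Leukocyte transcripts were also higher there, with Lyz2 at 3.14 and Clec4f at 1.88, and so were hepatocyte transcripts, with a free RNA list median of 0.71. In LSEC-like cells with no leukocyte marker UMI, 210 in Control and 124 in pIVCL, the interferon-gamma list had a median of 0.41 and the adhesion list 0.91, while the glycolysis median was 0.06. Too few MHC class II members were measured in those cells to give that list's median.

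**Figure D4:**
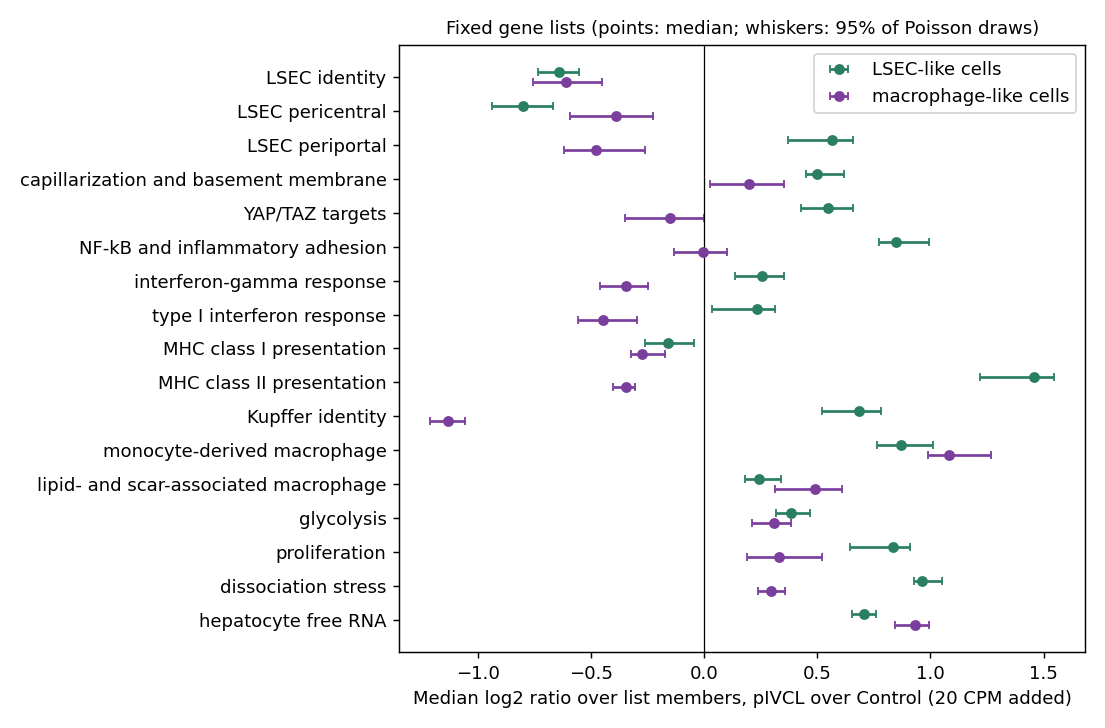
Median log2 ratio, pIVCL over Control, of 17 gene lists in LSEC-like and macrophage-like cells, with 95% of Poisson draws as whiskers. The LSEC identity list lies at -0.64 and the adhesion list at 0.85 in LSEC-like cells, and the Kupffer identity list at -1.13 in macrophage-like cells.

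Macrophage-like cells had lower levels of Kupffer cell genes in pIVCL and higher levels of monocyte genes. Of 15 Kupffer identity genes 14 were lower (median -1.13, percentile 0), among them C6 at -1.75, the folate receptor gene Folr2 at -1.63, Timd4 at -1.46 and Cd5l at -1.40. Of 15 genes of monocyte-derived macrophages 13 were higher (median 1.08, percentile 100), with Fn1 at 2.27, F13a1 at 2.23, S100a6 at 1.89 and Ly6c2 at 1.84. Part of this came with the larger monocyte/macrophage-like part of the class: in Kupffer-like cells alone the Kupffer identity median was -0.57 and the monocyte median -0.01. Kupffer-like cells were also split differently: the shallow cluster 2 held 56.4% of them in Control and 81.3% in pIVCL, and cluster 9, led by genes such as C6, Cd163 and Gbp2b, held 43.6% and 18.7%. Genes of lipid- and scar-associated macrophages had a median of 0.49, with 11 of 13 higher, Fabp5 at 1.38 and Cd63 at 1.32, against Lpl at -1.22.

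Interferon-responsive genes were lower in pIVCL macrophage-like cells. The interferon-gamma list had a median of -0.35 (percentile 0.13), with 16 of 19 members lower, among them Gbp3 at -1.05 and Irf1 at -0.86. The type I interferon list had a median of -0.45 (percentile 0.01), with 17 of 19 lower, among them Irf7 at -0.88 and Rsad2 at -0.85. Of 9 MHC class II genes 7 were lower (median -0.35, percentile 2.73, inside the central 95% of random lists), with H2-DMa at -0.62 and H2-Aa at -0.60. In Kupffer-like cells alone these medians were -0.39, -0.32 and -0.64.

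The highest single genes of macrophage-like cells were the granule genes Prtn3 (3.86), Elane (3.65), Mpo (3.58) and Ctsg (2.59). Prtn3 had 1 and 607 UMIs, a ratio of 455 (81.4 to 18010), and the others had 0 UMIs in Control. With the floor of 3 UMIs, Control lay 125-fold, 119-fold and 54.5-fold below pIVCL for Elane, Mpo and Ctsg. The lower bounds of their ratios were 101, 96.6 and 44.0. Of 1802 pIVCL UMIs of these genes, 1769 lay in 13 cells, so they describe a small group of immature myeloid cells and not the class. Mup20 (3.00), Gstm1 (2.22) and Cyp3a11 (2.17) are abundant hepatocyte transcripts, and the hepatocyte free RNA list had a median of 0.93 in these cells and 1.44 in Kupffer-like cells alone. The heat shock gene Hspa1a stood at 2.15, and the dissociation stress list had a median of 0.30 (percentile 99.3), with 14 of 17 members higher and 3 lower. The lowest were the interferon-induced Gbp2b (-2.98, from 232 to 12.0 CPM), the lectin gene Fcna (-2.43), Fabp7 (-2.03), Ptgis (120 UMIs in Control and 9 in pIVCL) and Pltp (-1.82). C6, Cd207 (-1.63), Ms4a8a (-1.63), Folr2 and the chemokine gene Ccl24 (-1.62) completed the lowest 10.

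Hepatocyte-like cells, 459 in Control and 1846 in pIVCL, had lower summed levels of pericentral genes in pIVCL. Cluster 20, led by genes such as Slc1a2, Glul and Cyp2e1, held 91 Control cells and 1 pIVCL cell, while cluster 11, led by genes such as Cyp2a5 and Cyp1a2, held 0 and 263. Without cluster 20, which takes most pericentral-leaning cells out of Control only, the pericentral list median was 0.45. The ratio of Glul was then 0.882 (0.764 to 1.02), that of Cyp2e1 0.686 (0.663 to 0.710) and that of Oat 1.39 (1.26 to 1.54). In the whole class Glul, the glutamine synthetase of the hepatocytes around the central vein, had a log2 ratio of -4.58 (1619 CPM in Control and 48.5 in pIVCL, a ratio interval of 0.0279 to 0.0321). It lies at chromosome 1, positions 153899944 to 153909723. The glutamate transporter gene Slc1a2 stood at -3.83 and Oat at -2.57. Of 14 pericentral genes 12 were lower (median -0.62, percentile 0), while the periportal list lay within the random range (median 0.20, percentile 86.3, 9 of 14 higher), with Cyp2f2 at 0.91. Mup17 (-3.05), Mup11 (-2.97) and Cyp2c69 (-2.90) were also among the lowest, and Mup20 (3.13), Selenbp2 (2.45), Gstm3 (2.10), Serpina7 (2.08) and Gstp1 (1.85) were the highest, with the caveat that Mup genes are near-identical copies. All 16 proliferation genes were higher (median 0.65), with Stmn1 at 1.23 and Ube2c at 0.93, but the median was 0.14 without cycling cluster 23, which held 10 Control and 77 pIVCL cells. All 16 type I interferon genes were higher (median 0.36), with Ifit1 at 1.11. Cluster 15 held 155 Control and 0 pIVCL cells, and cluster 6 held 8 and 444. With the stricter filter, which left 112 and 661 hepatocyte-like cells, the pericentral median was -0.27.

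**Figure D5:**
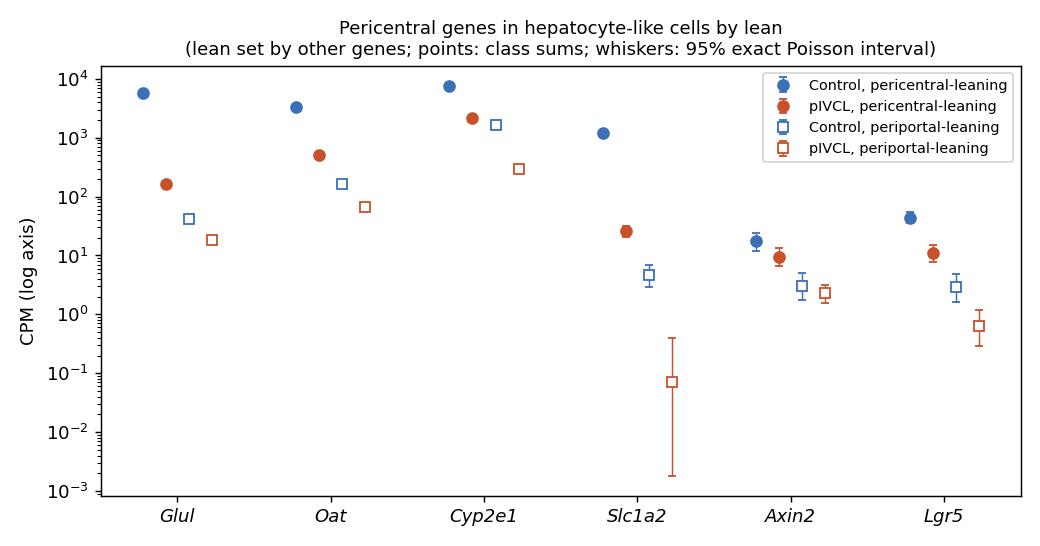
Levels of 6 pericentral genes (CPM, log axis) in pericentral-leaning and periportal-leaning hepatocyte-like cells of the Control and pIVCL libraries, with exact 95% Poisson intervals as whiskers. Glul in pericentral-leaning cells stands at 5692 CPM in Control, where 65 of the 86 cells are of cluster 20, and 163 in pIVCL, where 1 of 233 is.

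T cell-like cells, 192 in Control and 333 in pIVCL, had higher levels of naive T cell genes in pIVCL. All 8 members of the naive list were higher (median 0.80, percentile 100), with the transcription factor gene Tcf7 at 1.58 and S1pr1 at 1.33. The effector and residency list went both ways (median -0.17, 5 higher and 8 lower), with the residency receptor gene Cxcr6 at -1.46, Cxcr3 at -1.12 and Eomes at 1.67 (1 and 37 UMIs, a ratio of 46.2 with an interval of 7.79 to 1874). The chemokine genes Ccl4 (3.35) and Ccl3 (2.56) were among the highest, with hepatocyte transcripts such as Mup20, Scd1 and Cyp2f2. Mmp9 (-1.79), Socs2 (-1.73), Ckb (-1.73) and Rcbtb2 (-1.57) were the lowest with Cxcr6. Cluster 12, led by Cxcr6, Cd3g and Cxcr3, held 77.6% of Control and 25.8% of pIVCL T cell-like cells, and cluster 8, led by Cd8b1 and Tcf7, held 22.4% and 74.2%. The stress list had a median of 0.90 and the hepatocyte free RNA list 1.19.

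B cell-like cells, 135 in Control and 1033 in pIVCL, also came largely from different clusters, with cluster 0 holding 36.3% and 89.0% of them and cluster 14 holding 86 Control and 114 pIVCL cells. The heat shock genes Hspa1a and Hspa1b had 206 and 122 UMIs in pIVCL and 0 in Control. With the floor of 3 UMIs they were 16.1-fold and 9.51-fold higher, with lower bounds of the ratios of 12.9 and 7.62. The hepatocyte transcripts Mup20 (2.96), Cyp2f2 (2.22) and Gstm1 (1.95) were also among the highest, and the stress list had a median of 0.74. Slpi had 49 UMIs in Control and 0 in pIVCL, 69.8-fold lower with the floor of 3 UMIs (upper bound of the ratio 0.0183). Glipr1 stood at -1.38, Txndc5 at -1.01, Serpinb1a at -0.99 and Vrk1 at -0.95. With the stricter filter no Slpi UMI was left in these cells and Txndc5 stood at 0.28, so Slpi and Txndc5 depended on which cells were kept. MHC class II genes had a median of -0.25, with 8 of 9 lower.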

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

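The count among LSEC-like cells without leukocyte markers and the values of Kupffer-like cells alone were chosen after the data were seen, and the other tests in this part before their results were seen. The following 4 gene lists went in opposite directions in LSEC-like and macrophage-like cells, and the differences between the classes were not tested. The interferon-gamma response list had a median log2 ratio of 0.26 in LSEC-like and -0.35 in macrophage-like cells, and the type I interferon response list 0.23 and -0.45. The periportal endothelial list had 0.56 and -0.48, and the Kupffer identity list 0.69 and -1.13. The former list was made for endothelial cells and the latter for Kupffer cells, but their members need not be absent from other classes. In LSEC-like cells the Kupffer list members Id3 (1306 CPM in Control and 919 in pIVCL) and Slc40a1 (259 and 183) were lower in pIVCL, against 11 of 13 members higher. In macrophage-like cells the LSEC identity list was also lower (-0.61, 13 of 14 members lower). In LSEC-like cells the monocyte list was also higher (0.87, 10 of 10 higher), so RNA of other cells is not excluded for these lists. Irf1 stood at 0.81 in LSEC-like cells and at -0.86 in macrophage-like cells. In LSEC-like cells without leukocyte marker UMIs the interferon medians were 0.41 and 0.47, and in Kupffer-like cells alone they were -0.39 and -0.32.

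Cxcl9 was 4.14 times higher in LSEC-like cells of the pIVCL library. Leukocytes caught with LSEC-like cells are argued against, since no leukocyte-like class had more than 123 CPM, below the 275 and 1137 of LSEC-like cells. Leukocyte RNA could thus only lower the pIVCL level. The ratio of 4.37 (3.47 to 5.53) among cells with no leukocyte marker UMI could therefore hardly have come out otherwise. After thinning to 1000 UMIs the ratio was 4.84 (4.17 to 5.65). Thinning keeps each cell's expected Cxcl9 fraction, so this ratio cannot decide on lower depth per cell. At that equal depth, 17.2% of Control and 51.0% of pIVCL LSEC-like cells held a Cxcl9 UMI. Stress during dissociation stays open: the ratio was 5.11 among cells with the highest stress share and 1.74 and 1.54 in the other groups, where the lower bounds of 1.39 and 1.31 lay below the 1.5 set beforehand, so much of the excess may come with the stress genes. From the lowest to the highest stress group Cxcl9 was 203, 297 and 298 CPM in Control and 353, 457 and 1525 in pIVCL. Immediate-early genes are also induced in living tissue, so the list does not separate handling from congestion, and an effect of the ligation stays open as untested, since each group was 1 library.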

How the results depend on the processing

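The removal of high doublet scores, cells without leukocyte marker UMIs, cells with at least 2000 UMIs, lists without Fabp4 and Cd36, Kupffer-like cells alone, and classes without their cycling clusters were chosen after the data were seen. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. Unless the construction shows it, the cause of a shift was not tested.

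The macrophage share ratio of 1.39 became 1.05 with the stricter filter, 1.04 with classes set per cell, 1.21 for Kupffer-like cells alone, 1.75 without hepatocyte-like cells, 2.57 relative to macrophage-like plus LSEC-like cells, and 0.795, the other direction, among leukocyte-like cells. The Cxcl9 ratio in LSEC-like cells ranged from 3.92 to 4.84 over 13 alternatives, and moved beyond its interval to 4.51 with the stricter filter, 4.72 as a mean over cells and 4.84 after thinning. The pericentral over periportal Cxcl9 ratio moved in Control to 0.361 without leukocyte markers, 0.350 with z-scores and 0.324 with neighbour averaging. In pIVCL it moved to 0.478 with z-scores, 0.260 with neighbour averaging, 0.494 with core lists, 0.489 with vascular endothelial-like cells included and 0.41 without Fabp4 and Cd36.

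The LSEC identity median moved to -0.76 and the interferon-gamma median to 0.37 with 5 CPM added, and the latter to 0.41 without leukocyte markers. The Kupffer identity median moved to -1.05 with both other size factors, -1.48 in cells with at least 2000 UMIs and -0.57 in Kupffer-like cells alone. The monocyte list moved to 1.55 with the stricter filter, 1.37 at resolution 2, 1.30 with 15 neighbours, 1.42 in cells with at least 2000 UMIs and -0.0129, the other direction, in Kupffer-like cells alone. The hepatocyte pericentral median moved to -0.27 with the stricter filter, -0.71 with none, -0.76 with free RNA out of the totals and -0.79 with 5 CPM added.

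Of 1658 list medians under the alternatives, 1604 kept their direction and 54 did not, of which 43 belonged to lists whose reported median lay inside the central 95% of random lists. Of 910 values of the 70 named genes, 900 kept their direction, 4 reversed and 6 were 0 because no UMI was left (Slpi under 3 alternatives, and Elane, Mpo and Ctsg in Kupffer-like cells alone). In Kupffer-like cells alone proliferation (-0.22), stress (-0.19) and F13a1 (-0.0909) reversed, and 5 lists inside the range also changed sign, among them iron handling (-0.19 to 0.14) and inflammatory macrophage genes (0.14 to -0.19). Without the cycling clusters the proliferation median moved from 0.83 to 0.28 in LSEC-like and from 0.65 to 0.14 in hepatocyte-like cells. The LSEC iron list reversed to -0.0812 with the stricter filter and -0.24 with at least 100 UMIs, and LSEC hypoxia to -0.0149 without leukocyte markers. Txndc5 in B cell-like cells reversed to 0.28 with the stricter filter, 0.25 with 15 neighbours and 0.20 without high doublet scores, and their LSEC identity list to 0.37 with doublets kept. In hepatocyte-like cells the shear list reversed to 0.13 with the stricter filter and 0.0782 with at least 100 UMIs, the Kupffer list to 0.0462 with the former and the stellate quiescence list to 0.0476 with the latter. Clusters stayed unnamed in 4 alternatives: 1 with the stricter filter (682 Control LSEC-like cells), 2 with no filter (1161), 1 with doublets kept (847) and 3 at resolution 2 (916), and which cells the unnamed clusters held was not tabulated. No scaling moved the median of all genes by over 0.1.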

Other observations

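The tests of LSEC-like recovery and of Wnt targets were chosen after the results were seen, and that without the Glul-rich cluster after the cluster counts but before its own value was seen. Hepatic stellate-like cells numbered 182 in Control and 86 in pIVCL, under the 100 cells required for a comparison. Of 16 stellate activation and collagen genes 13 were higher in pIVCL and 3 lower (median 1.23), with log2 ratios of 3.07 for Col1a1 (156 and 1456 CPM), 1.85 for Col3a1 and 2.31 for Lox. Eln, which is not on that list but is a marker used here for fibroblasts and smooth muscle, stood at 2.76. The highest log2 ratios were those of S100a6 (3.92) and Clec3b (3.43). Mfap5 had 2 and 90 UMIs, a ratio of 106 (28.5 to 888), and as Clec3b and Mfap5 are also fibroblast genes, other mesenchymal cells in this class are not excluded. All 11 measured genes of quiescent stellate cells were lower (median -1.45), with Hgf at -1.97, Ngfr at -1.98, Angptl6 at -1.94 and Ecm1 at -1.71. Transcripts of other cells and stress moved in the same cells, with medians of 0.80 for the Kupffer identity, 0.84 for the monocyte, 1.16 for the MHC class II and 0.49 for the stress list.

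Vascular endothelial-like cells numbered 124 in Control and 91 in pIVCL. Ly6a stood at 3960 CPM in Control and 354 in pIVCL, while Nts (3.62) and Lyve1 (3.32) were among the highest log2 ratios beside the leukocyte genes Nkg7 (3.35), Ptprc (3.32) and Il2rb (3.10). Cluster 18 held 91 Control and 17 pIVCL cells of this class and cluster 19 held 33 and 74. Among barcodes removed by the cell filter, Cxcl9 stood at 16.6 CPM in Control (13.1 to 20.7) and 5.79 in pIVCL (4.43 to 7.43). These barcodes were summed over all classes, so the difference may follow their class mix and cannot be set against that in LSEC-like cells.

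Pericentral genes were lower in hepatocyte-like cells of the pIVCL library. Shallow barcodes and the 25% mitochondrial limit are argued against by list medians of -0.61 in the deeper cells (260 in Control and 784 in pIVCL) and -0.71 with no filter, although the stricter filter gave -0.27. Fewer cells of the Glul-rich layer and a lower level in them cannot be told apart: the Glul ratio of 0.0287 (0.0264 to 0.0311) among pericentral-leaning cells (18.7% of Control and 12.6% of pIVCL hepatocyte-like cells) compared 86 Control cells, 65 of them in cluster 20, with 233 pIVCL cells, 133 of them in cluster 11. The median of 0.45 without cluster 20 decides nothing either, since it takes these cells out of Control only. With Wnt2 at -2.50 in LSEC-like cells, loss of an endothelial Wnt signal may play a part, as 7 known Wnt targets had a median of -2.24 and the other 7 members -0.17 (a difference of -2.07), but loss of cluster 20 cells could give the same, and without that cluster Lgr5 (3 and 48 UMIs, ratio 3.99, 1.29 to 20.0) and Oat (1.39, 1.26 to 1.54) were higher in pIVCL.

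B cell-like (4.97% and 19.0%), neutrophil-like (0.110% and 1.62%) and erythroid-like cells (0.147% and 1.25%) held more of the pIVCL than of the Control library, while T cell-like cells held 7.07% of Control and 6.13% of pIVCL. Lower recovery of LSEC-like cells alone is argued against, since it would leave leukocyte classes in proportion, whereas B cell-like cells per Kupffer-like cell were 3.15 times higher (2.53 to 3.94). More blood in the suspension cannot be told apart from a change in the tissue: circulating over resident gene UMIs in 27 and 88 NK/ILC1-like cells were 1.32 times higher, with an interval of 0.938 to 1.86 that lies on both sides of the 1.5 set beforehand. The higher naive T cell gene S1pr1 and the granulocytes may equally reflect either.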
